A study of Mus musculus with 31 samples.

How the data were processed

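Whole-brain RNA of 31 BXD/TyJ strains was hybridised against C57BL/6J whole-brain RNA on 2-colour glass arrays, 1 array per strain. Per the labels, RNA from 3 animals of a strain was mixed, 20 ug of it was reverse transcribed and labelled with Alexa Fluor 647, and 20 ug of reference RNA with 2 ug of a spike-in mix was labelled with Alexa Fluor 555. The deposited values are log ratios, taken as log2, in 1 table of 23040 spots by 31 arrays with 0 missing values. Per the submitters' processing notes, R 2.0.0 and limma were used, with no role given. Background correction, normalization within arrays and spot filters are not given in the sources used here. All 31 columns held the same sorted values, with a largest difference of 0, so the deposited arrays had been quantile normalised to each other. The common median was 0.01, the SD 0.60 and the range −4.07 to 4.95. Quantile normalisation removes differences between arrays in the distribution of log ratios, and any true shift of the whole distribution with them.

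The scale, centring and direction of the table were not stated. Log2 was taken because limma writes log2 ratios, and strain over C57BL/6J was taken from the channel order and titles in the labels. Signs and sizes depend on these choices, whereas counts of calls do not depend on the log base except in the test against 1.2-fold. Scanner files and intensities were not analysed here, so no probe could be called dim or saturated.

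Gene symbols came from the platform annotation, in which 16874 probes had 1 symbol, 134 several and 6032 none. Probes with several symbols were left unnamed. List members under an older symbol were matched through RefSeq synonyms unless that symbol is itself in current use. Of the named probes, 16196 matched a RefSeq gene of assembly GRCm38.p6 by Entrez identifier, which changed 0 symbols. That table also gave the order of genes on chromosomes; no coordinates were used. Probes of a gene were averaged, which gave 15096 genes, 1048 of them with several probes, and 6166 spots without a single symbol, in all 21262 features. Place within a run of 8 spots was read from probe numbers, with 48 blocks of 480 spots; that it reflects successive printing is an assumption.

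The groups, tests, gene lists, alternatives and the rule for genes to name were fixed before the data were examined. The mean log ratio was tested against 0 with limma (lmFit with an intercept and eBayes, two-sided). The reference stands for 1 control sample, so this test leaves out the spread of the control and any fixed effect of dye or spot. The spread between strains was tested by setting each variance against the scaled F distribution fitted with limma's fitFDistRobustly (one-sided; scale 0.0635, second degrees of freedom 3.56). For division into 2 parts, the largest share of variance between parts was taken over all divisions with at least 5 strains on each side, with a one-sided p from 1000000 simulated normal samples. Neighbouring genes were pairs within 10 places on a chromosome, leaving out pairs with the same symbol stem, against 10000 shuffles of positions; in the shuffles the mean over all pairs stood for that between chromosomes. Strain sets were compared with limma (7 strains against 24, two-sided). Gene lists with at least 4 measured members were tested with camera (preset correlation, with an estimated one as alternative) and fry, and for covariation against 10000 random lists of the same size (one-sided). For probes of one gene, the first 2 probes by number were correlated, with 10000 random pairings (one-sided). Benjamini-Hochberg adjustment was used throughout at 0.05.

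The rule for named genes took only features with a symbol: the 12 highest and 12 lowest means among calls with the same sign on every array, the 20 widest interquartile ranges among spread calls, the 15 largest shares for 2 parts, the 10 largest set differences in each direction, up to 4 members of each list with the smallest adjusted p, and the check genes Nnt, Gabra2, Alad and Glo1. The rule on spread named none. Members of the lists named for their correlation, probe pairs and pituitary genes on single arrays were chosen after their values were seen.

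Each main procedure except camera and fry was tested on simulated data. For the mean, 78% of genes with a shift of 0.25 and 99% with 0.5 were recovered, with 7 false calls among 15096 genes. For strain sets, 69% at 0.5 and 97% at 1 were recovered, with 18 false calls. The test for 2 parts recovered 2% of genes at a gap of 3 SD and 80% at 5 SD, with 2 false calls. Apart from the changes put in, these simulations drew values independently for each gene and array. They lack the array groups of the real data, so their numbers of false calls need not hold for the real arrays. The spread test recovered 0% at 9 times and 3% at 100 times the variance and so has little power here. For neighbouring genes, a difference of 0.0303 was obtained at a shared variance of 0.2.

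One departure from the design was needed. The comparison of neighbouring genes was planned for genes past the spread test, which left none, so its value over all 14606 ordered genes, laid down in advance as another setting, was reported. Other windows, component removal and rank correlation on all genes, and the tenth of genes with the widest interquartile range, were added after the data were seen. Removal of the first 3 components, leaving out the 7 arrays apart on the first component or single strains, and the scan of each list on each strain were likewise added. Filters on missing values removed nothing. Strain genotypes were not used here, so no locus was mapped. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and statmod 1.5.0.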

Results

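Whole-brain RNA from 31 BXD/TyJ mouse strains was measured on 2-colour glass arrays, with 1 array per strain. BXD strains are recombinant inbred lines derived from crosses of C57BL/6J with DBA/2J, so that each line is homozygous at most loci for the allele of one parent or the other. All animals were males aged 8 weeks, and the RNA of 3 animals was pooled for each strain. The strain RNA carried Alexa Fluor 647 and a whole-brain RNA reference from C57BL/6J carried Alexa Fluor 555 on every array, without dye swaps. Of the strains, 24 had numbers up to 32 and 7 had numbers from 33 to 42. The series title names genetic differences in gene expression within and between individuals as its subject. Each array gave 1 log ratio for each of 23040 spots, of which 16874 had 1 gene symbol, and these covered 15096 genes. The number of arrays limits the precision, and signal over background was not used here. Because each strain had 1 array of 1 pool, differences between strains could not be separated from differences between arrays, and p-values measure the spread between these arrays.

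The arrays fell into separate groups. On the first principal component, which held 28.7% of the variance, the arrays of BXD6, BXD8, BXD20, BXD23, BXD28, BXD36 and BXD38 scored from 0.27 to 0.32 and the other 24 from −0.21 to 0.05. Mean pairwise correlation was 0.659 within these 7 arrays, 0.718 within the other 24 and 0.446 between them. On the second component, with 11.9% of the variance, BXD15, BXD22, BXD27, BXD33, BXD34, BXD39, BXD40 and BXD42 scored from 0.25 to 0.32 and the other strains from −0.22 to 0.08. Thus 5 of the 7 strains numbered from 33 stood in the second of these groups and the remaining 2 in the first. Both groups were noticed in the data, and the labels give no batch.

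**Figure D1:**
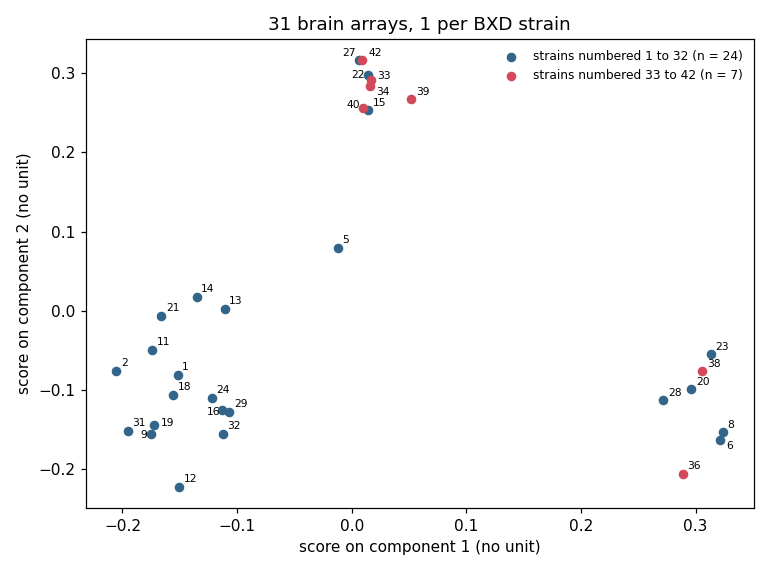
Scores of the 31 arrays on the first (x axis) and second (y axis) principal component of all 21262 features, without unit. Each point is the array of 1 strain, labelled with its number, and the 7 arrays with first-component scores from 0.27 to 0.32 lie apart on the right.

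The first comparison asked which genes had a log ratio against C57BL/6J that differed from 0 over the strains. Ratios were taken as strain over C57BL/6J from the order of the channels and the titles in the labels, but this direction was not settled, so signs are reported as those of the log ratio and all of them would turn in the other direction. The log base was not stated either and was taken as 2. By limma's moderated test, 16176 of 21262 features (genes, or spots without a symbol) differed from 0, 8960 with a positive and 7216 with a negative mean. Among named genes the numbers were 6302 positive and 5114 negative of 15096, adjusted over named genes alone, and 1504 genes passing the test had the same sign on all 31 arrays. Against a change of 1.2-fold in place of 0, 5938 features passed, with 2630 positive and 3308 negative.

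The highest means with the same sign on all arrays were those of Pkmyt1, a kinase that inhibits Cdk1, at 1.24 ± 0.10 (SE, n = 31) and of Znrf2, a ubiquitin ligase, at 1.11 ± 0.08. Rbms1, encoding an RNA-binding protein, followed at 1.05, and Fcho1, which acts in clathrin-mediated endocytosis, at 1.02. Taf8, a subunit of the transcription factor TFIID, had a mean of 1.00 ± 0.05. The mean was 0.98 for the inflammasome gene Nlrp6, 0.96 for the tubulin deacetylase gene Hdac6 and 0.95 for both Gipc2 and Fgfrl1. Means of Numa1, a spindle organiser, Lysmd1 and Pcm1, a centriolar satellite protein, lay between 0.93 and 0.94. The lowest means were larger in size. Gadl1, related to glutamate decarboxylase, had a mean of −3.20 ± 0.12 (SE, n = 31; limma adjusted p = 5.48e-21). It was followed by 1600010M07Rik at −3.11, Mfsd14b, a member of a transporter family, at −2.72, the sulfotransferase gene Sult1c2 at −2.57 and Scel at −2.22. Ifi204, an interferon-inducible gene, had a mean of −2.17, Rad54l2 of −2.09, the anthrax toxin receptor gene Antxr2 and 4930402D18Rik each of −2.05. 2310030A07Rik, B230217C12Rik and Arhgap19 had means between −2.02 and −1.99.

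The control was the 231 spots annotated to Gapdh at the eighth place in each run of 8 spots. By their annotation they measure 1 transcript. They lay in 4 of the 48 blocks of the array, and their mean pairwise correlation over strains was 0.156. Of these, 188 (81.4%) differed from 0, 41 with a positive and 147 with a negative mean, against 76.2% of all spots. Against a change of 1.2-fold, 34.2% of Gapdh spots and 28.2% of all spots passed. Gapdh means ran from −1.43 to 1.09 with an average of −0.22 and an SD of 0.39. The SD of means was 0.49 for other named probes at the eighth place and 0.41 for all named probes. Of the named genes, 3 lay above the highest and 118 below the lowest Gapdh mean, and 90 of those 118 had their probe at the eighth place in each run of 8 spots. Other named probes at that place, where the Gapdh spots had been taken, had a mean log ratio of −0.54 (n = 1951) against −0.01 to 0.08 at the other 7 places. Among the 12 lowest genes, Ifi204, Rad54l2, Antxr2, 4930402D18Rik, 2310030A07Rik and Arhgap19 lay at that place, and none of the 12 highest did. Among the 13187 named genes with no probe there, 9781 differed from 0, 6157 positive and 3624 negative.

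**Figure D2:**
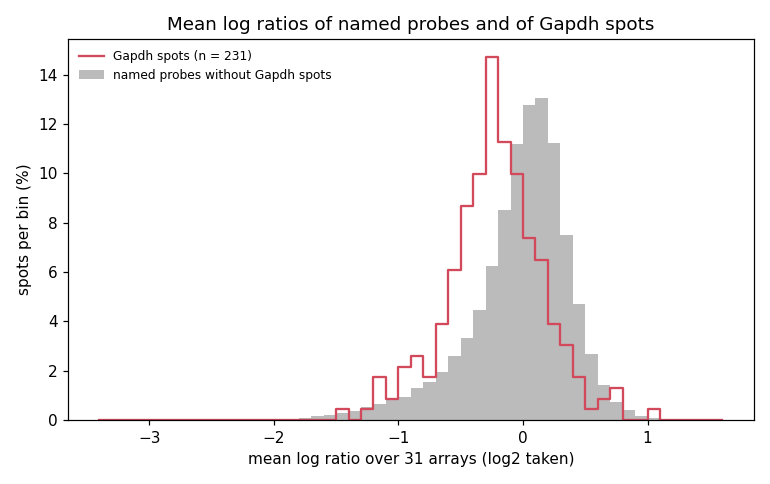
Distribution of mean log ratios over 31 arrays (x axis, log2 taken) as the percentage of spots per bin (y axis), for named probes without Gapdh spots (grey bars) and for the 231 Gapdh spots (red line). Gapdh means extend from −1.43 to 1.09.

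Genes with a known difference between the parental strains were examined as a check. Nnt, which carries a deletion in C57BL/6J, had a mean of −0.03 (limma adjusted p = 0.319) and Alad, duplicated in DBA/2J, of 0.01 (limma adjusted p = 0.764), so that neither differed from 0. Glo1, also duplicated in DBA/2J, had a mean of 0.33 ± 0.06 (SE, n = 31) with 26 of 31 arrays above 0. Gabra2, less expressed in C57BL/6J because of a private variant, had a mean of −0.73, but its 2 probes gave −0.10 and −1.37. Positive values had been foreseen for all 4 genes, so they did not settle the direction. A further 384 spots without a symbol, at 8 consecutive places of each block, had a mean of 1.59. Another 384 such spots, at the next 8 places, had a mean of −0.07. The labels name a spike-in mix in the reference channel alone, but whether either run of spots detects it is not given in the sources used here. If the first run does, its positive mean goes against strain over C57BL/6J.

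The 25 gene lists fixed for brain cell types, regions and pathways were compared with the other genes. None stood apart in camera with its preset correlation (adjusted p from 0.635 to 0.954; 0 lists at an unadjusted p under 0.05), and with an estimated correlation adjusted p ran from 0.913 to 0.972. By fry's mixed test, members changed in either direction in 24 of the 25 lists (not in blood, adjusted p = 0.0579), and by fry's directional test 18 lists moved on balance one way; neither test compares a list with other genes. The counts that follow are of limma calls over all features. Adjusted over the list alone they were the same for every list except microglia.

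Among cell-type markers, 8 of 13 oligodendrocyte and myelin genes had positive and 3 negative means. Cnp and Mal, both myelin components, had means of 0.42 ± 0.05 and 0.44 ± 0.07 (SE, n = 31), while the glial connexin gene Gjc3 had −0.43 ± 0.04. In the endothelial list 8 of 11 genes were positive and 2 negative, with the tight junction gene Cldn5 at 0.53, the VEGF receptor gene Kdr at 0.45 and the glucose transporter gene Slc2a1 at −0.59. Of 11 astrocyte genes, 2 were positive and 5 negative, and the gap junction gene Gja1 had the lowest mean of those named, −0.99 ± 0.10, with Sox9 at −0.51 and Aldoc at −0.36. Gfap had a mean of 0.22, with 0.34 and 0.09 for its 2 probes. Of 16 neuronal genes, 6 were positive and 4 negative, among them the synaptic vesicle gene Syt1 at 0.59 and the GABA-synthesis gene Gad2 at −0.60, whose 2 probes gave −0.55 and −0.65. Of 11 microglial genes, 3 were positive and 4 negative, and 2 and 4 adjusted over the list alone. Tyrobp, encoding a signalling adaptor, had a mean of 0.59, whereas the receptor genes Cx3cr1 at −0.64 and P2ry12 at −0.67 both lay at the eighth place. In the choroid plexus list 5 of 11 were positive, including the water channel gene Aqp1 at 0.31, and 3 negative, including the transthyretin gene Ttr at −0.43. Of 4 blood genes none was positive and 3 were negative, with means of −0.27 for Bpgm, −0.22 for Slc4a1 and −0.15 for Alas2; the haemoglobin gene Hba-a1 stood at 0.01 and did not pass.

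Among regional markers, 6 of 9 striatal genes were positive and 2 negative. The dopamine receptor gene Drd2 had a mean of 0.40 ± 0.03 (SE, n = 31) with all 31 arrays above 0, Pde10a had 0.53 and Pdyn 0.38, whereas the enkephalin precursor gene Penk, at the eighth place, had −1.27. In the cerebellar list 5 of 12 were positive, such as Cbln1 at 0.41 and Neurod1 at 0.42, and 3 negative, such as Gabra6 at −1.02 and Pvalb at −0.19, both at the eighth place. Of 11 hypothalamic peptide genes, 7 were positive and 2 negative, with Npy at 0.38, Trh at 0.16, Cartpt at −0.42 and Pmch at −0.30. In the pituitary list 4 of 9 were positive, including the prolactin gene Prl at 0.54 and Ghrhr at 0.45, and 1 was negative, Fshb at −0.94 on an eighth-place probe.

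Among GABA-A receptor subunits 2 of 10 were positive and 5 negative. Gabra5 had a mean of −1.80, Gabra3 of −1.43 and Gabra6 of −1.02, these 3 all at the eighth place, and 5 of the 10 genes had a probe there. Ionotropic glutamate receptor genes were positive in 9 of 13 and negative in 3, with the AMPA subunit gene Gria2 at 0.49, Grik5 at 0.62 and Grid1 at −0.51. Gria1 had −0.28, with −0.73 and 0.17 for its 2 probes. Of 13 immediate early genes, which respond quickly to neuronal activity, 5 were positive and 4 negative. Fos at 0.91 ± 0.09 and Btg2 at 0.65 ± 0.04 (SE, n = 31) were above 0 on all 31 arrays, Egr1 at −0.41 was below 0 on all of them and Junb at −0.51 on 30. Of 12 circadian clock genes, 3 were positive and 5 negative, with Clock at −0.71 (−0.46 without the 7 arrays apart on the first component), the clock output gene Dbp at −0.53 and Cry2 at 0.19.

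Cytosolic ribosomal protein genes were positive in 22 of 37 and negative in 8, with Rps3 at 0.80 ± 0.08 (SE, n = 31) and Rpl4 at −0.39 ± 0.03. The 2 probes of Rpl23 gave −1.03 and −0.16. Of 51 genes of oxidative phosphorylation, 27 were positive and 13 negative. Those with the smallest adjusted p were all negative, namely Ndufb10 at −0.93 and Ndufa8 at −0.82, both at the eighth place, Cox8a at −0.69 and Uqcrh at −0.63. Glutathione genes were positive in 8 of 21 and negative in 8, with Gstp1 at 0.49, Gss at 0.45, Gclm at −0.97 and Gsr at −0.48. In cholesterol synthesis 6 of 11 were positive, among them Sqle at 0.46 and Cyp51 at 0.36, and 3 negative. Of 10 heat shock genes and chaperones, 3 were positive, including Hspb1 at 0.51, and 4 negative, including Cryab at −1.20 and Hspa1a at −0.78, both at the eighth place.

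In the MHC list 7 of 14 genes were positive and 6 negative, with H2-Ke6 at 0.89 and the class II genes H2-DMb1 at −0.48, H2-Eb1 at −0.38 and H2-Ea at −0.33. Interferon response genes were positive in 6 of 12 and negative in 4, with Rsad2 at 0.46, Ifit3 at 0.42, Gbp2 at −0.76 and, on an eighth-place probe, Psmb9 at −0.66. In the list of genes known to differ between DBA/2J and C57BL/6J, 6 of 12 were positive, with complement C4b at 0.59 ± 0.05 (SE, n = 31) above 0 on all arrays and the dioxin receptor gene Ahr at 0.35, and 3 were negative, with complement Hc at −0.74. Of 5 genes with variants private to C57BL/6J, 1 was positive, Ide at 0.42, and 3 negative, Gabra2, Entpd4 at −0.30 and Wdfy1 at −0.13. Of 7 Y-linked genes and Xist, 1 was positive, Eif2s3y at 0.43, and 2 negative, Usp9y at −0.53 and Uty at −1.95 on an eighth-place probe; Xist at −0.05 did not pass. For the lists of cerebellum, choroid plexus, immediate early genes, microglia, glutathione, MHC and neurons, the median, the mean and the tests did not share 1 sign, and centring the arrays on their median of 0.01 turned the sign of the neuronal median and the cerebellar mean. A setting chosen after the data were seen left genes at the eighth place out of both the lists and the genes compared with them. The camera direction then turned for the lists of GABA-A receptor subunits, heat shock and neurons. It also turned for differences between DBA/2J and C57BL/6J, choroid plexus and immediate early genes, which lost no member, so only the genes compared with them had changed. None of these lists passed either way.

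Members of 3 gene lists covaried over the strains. Cytosolic ribosomal protein genes had a mean pairwise correlation of 0.432 over the 31 strains, against a 95th percentile of 0.0249 for random lists of 37 genes (one-sided permutation p = 0.0001, adjusted p = 0.00125 over 25 lists). The correlation with the rest of the list was positive for 35 of 37 members and was highest for Rps14 at 0.638 and Rpl19 at 0.635, while Rpl23 had −0.460. Genes of oxidative phosphorylation had a mean correlation of 0.194 (permutation p = 0.0001, adjusted p = 0.00125), positive for 44 of 51 members, among them Cox6c at 0.388 and Cox6a1 at 0.347. Cerebellar genes had 0.174 (permutation p = 0.0024, adjusted p = 0.0200), positive for 11 of 12, with En2 at 0.303 and Pvalb at 0.292. The smallest p that 10000 random lists can give is 0.0001. The other 22 lists did not pass. The nearest were immediate early genes at 0.109 (adjusted p = 0.0875), followed by genes with variants private to C57BL/6J at 0.186 (0.0256 without BXD6), Y-linked genes with Xist at 0.129, GABA-A receptor subunits at 0.106, pituitary genes at 0.0998, hypothalamic peptide genes at 0.0792 and myelin genes at 0.0712 (each adjusted p = 0.142). The remaining 15 lists ran from −0.0832 for blood genes to 0.0598 for astrocyte genes, with neuronal genes at 0.0358 and microglial genes at −0.00770.

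Ribosomal and oxidative phosphorylation genes passed again with the first 3 components removed, at 0.219 and 0.115. Without the 7 arrays apart on the first component they also passed, at 0.417 and 0.208. Both settings were chosen after the data were seen. Leaving out the 7 arrays keeps those high on the second component, so array groups remain in that setting. The cerebellar list passed with the first 3 components removed (0.0737, adjusted p = 0.0417) and without BXD6 (0.180, adjusted p = 0.0192), but not with the first component removed (mean correlation 0.0600, adjusted p = 0.136) or without the 7 arrays (0.0123, adjusted p = 0.458).

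**Figure D3:**
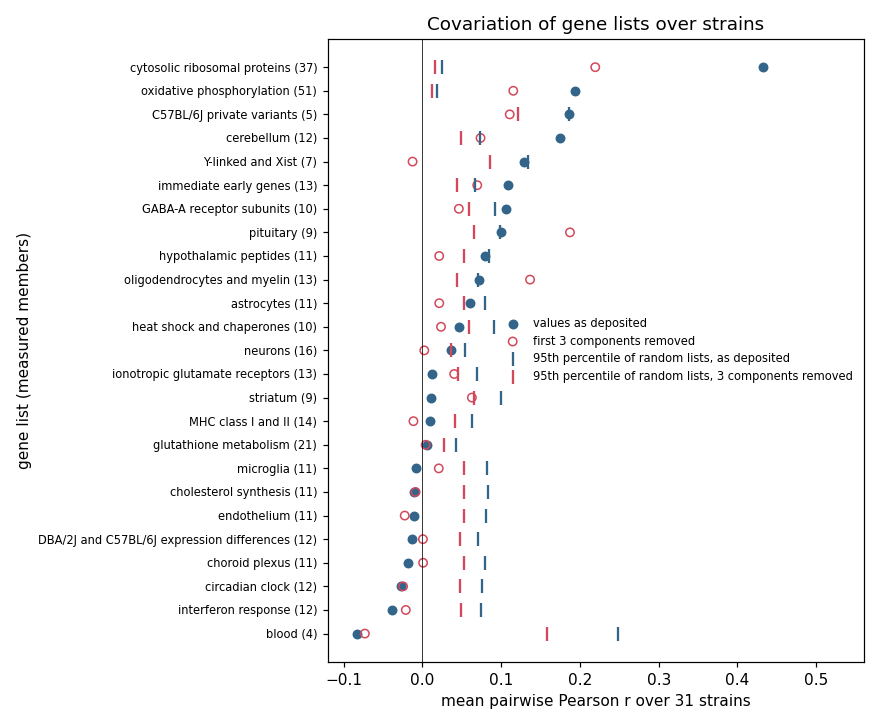
Mean pairwise Pearson correlation over 31 strains (x axis) of the members of each of 25 gene lists (y axis, number of measured members in parentheses), with values as deposited (filled) and with the first 3 components removed (open). Vertical ticks mark the 95th percentile of random lists of the same size, and the ribosomal list lies at 0.432 and 0.219.

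Probes of the same gene gave the replicate measure of the design. Over the 1048 genes with 2 or more probes, the median correlation over strains between the first 2 probes was 0.0265, above the 95th percentile of 0.0206 for random pairs (one-sided permutation p = 0.0188). With the first component removed it was 0.00589 (permutation p = 0.283) and with the first 3 removed 0.0221 (permutation p = 0.0051). Values of named genes rest on the platform annotation, and whether part of the probes carry a wrong symbol was not tested. A correlation above 0.5 was reached by 77 genes, against a mean of 60.4 in random pairings (permutation p = 0.0154). With the first 3 components removed the number was 21 against 10.2 (permutation p = 0.0021). The highest pairs then were those of Ablim1, an actin-binding protein, at 0.752, the neuronal membrane glycoprotein gene Gpm6a at 0.743 and Rpl35a, a ribosomal protein gene, at 0.698. These 3 genes were chosen after their values were seen. The mean log ratios of the first 2 probes correlated over the 1048 genes, which are not independent replicates, with r = 0.0336 (permutation p = 0.142), and had the same sign in 50.5% of them.

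No gene passed the test for spread between strains, which compared its variance with that of features in general. By limma's robust fit of the variance distribution, 0 of 21262 features passed, with a smallest adjusted p of 0.794 and 1142 features (333 named genes) at an unadjusted p under 0.05. The same number, 0, was reached with the median absolute deviation in place of the variance. In simulated data the test recovered 0% of genes with 9 times and 3% of genes with 100 times the usual variance, so the result does not show that genes vary alike. Gapdh spots had a median SD over strains of 0.31 and named genes of 0.27, and 29 named genes exceeded the highest Gapdh SD of 0.92.

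A single locus with 2 parental alleles would divide the strains into 2 parts, and 471 features, 298 of them named genes, divided more sharply than samples from a normal distribution (simulated p, one-sided, adjusted; 2590 at an unadjusted p under 0.05). The share of variance between the parts was highest for 4930511M06Rik at 94.5%. Its values ran from −2.72 to −1.49 in 6 strains, all among the 7 arrays apart on the first component, and from −0.00 to 0.63 in 25. The circadian gene Clock followed at 93.6% and Fancd2os at 93.4%, and in both the lower part held exactly the 7 arrays apart on the first component. For Clock these lay from −1.75 to −1.34 and the other 24 from −0.68 to −0.25. Nlrp4c had 91.2% with a lower part of 5 strains, also all among those 7 arrays. Without those arrays 4930511M06Rik, Clock, Fancd2os and Nlrp4c did not pass. The gene 4930522O17Rik had 90.1% with parts of 21 and 10. In the copper chaperone gene Atox1 (92.0%), the chemokine receptor gene Cxcr2 (92.0%), Acyp1 (91.3%), Serpinb9c (91.2%), the tissue factor gene F3 (90.8%), Fmnl1 (90.3%), Ccdc178 (90.2%), Aldh1a7 (90.0%) and Ercc6l (90.0%) the lower part held 15 or 16 strains, including all 7 of those arrays. The sphingosine phosphate receptor gene S1pr2 (91.6%) had parts of 17 and 14, and most of the 7 arrays lay in its upper part. These 10 genes all had their probe at the eighth place.

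The adjusted p was 0.000664 for each of these 15 genes, and 1e-06 is the smallest p that the simulations can give. Of the 471 features, 68 divided exactly as the 7 arrays and 135 within 1 strain of it. With the first component removed 7 features passed, with the first 3 removed 0, and without the 7 arrays 155, of which 53 were among the 298 genes.

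Linked genes share parental haplotypes in these strains, so neighbouring genes were compared with genes on other chromosomes. Over 14606 genes, the mean squared correlation over strains was 0.0964 for genes within 10 places of each other and 0.0959 for genes on different chromosomes. The difference of 0.000558 was small and exceeded most shuffles of gene positions (one-sided permutation p = 0.024, 10000 shuffles). It was 0.00120 within 3 places (permutation p = 0.0097), 0.000186 within 30 places (permutation p = 0.133) and 3.81e-05 within 10 places with the first 3 components removed (permutation p = 0.406). The test had been planned for genes that pass the spread test, of which there were none, so the value over all genes, also laid down in advance, is given.

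The last comparison set the 7 strains numbered from 33 against the 24 numbered up to 32, which came from separate rounds of inbreeding. By limma, 102 features differed, 51 with a higher and 51 with a lower log ratio in strains numbered from 33, among them 71 named genes (4301 features at an unadjusted p under 0.05). The orphan receptor gene Gpr165 had a mean of 1.19 ± 0.28 (SD, n = 7) in the strains from 33 and 0.20 ± 0.49 (SD, n = 24) in the others, a difference of 0.98 ± 0.19 (SE; limma adjusted p = 0.0193). In the other direction of the ratio, higher and lower would change places. The log ratio of the metalloproteinase gene Mmp1b was higher by 0.69, that of Gpr153 by 0.68, Retnlb by 0.66, Tyms-ps by 0.60 and the carboxypeptidase gene Cpd by 0.60. Log ratios of P3h4, the melatonin receptor gene Mtnr1b, 2900079G21Rik and the interleukin-18 binding protein gene Il18bp were higher by 0.52 to 0.56. Differences were −1.19 for Fam174c, −1.16 for 4930402F06Rik, −1.14 for 2700070H01Rik and −1.12 for the ubiquitin ligase gene Ubr3. Slc25a4, the mitochondrial ADP/ATP carrier, had a mean of −0.09 ± 0.37 (SD, n = 7) against 0.73 ± 0.48 (SD, n = 24), a difference of −0.82. Cnih3, which encodes an AMPA receptor auxiliary subunit, Perp, the cohesin gene Smc1b, Sar1b and Ccdc58 had differences from −0.75 to −0.65. Fam174c, Ubr3, Smc1b, Sar1b, Ccdc58, P3h4 and Mtnr1b had their probes at the eighth place. Values of 2700070H01Rik varied widely among the 7 strains, with an SD of 1.24.

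With the first 3 components as covariates 0 features passed, and the differences were then −0.22 for Fam174c, −0.26 for 4930402F06Rik, −0.13 for Ubr3 and −0.08 for Sar1b, but 0.66 for Gpr165 and −1.04 for 2700070H01Rik. With the first component as a covariate 67 passed, and without the 7 arrays apart on that component 3375. In that last setting all 5 remaining strains numbered from 33, and 3 of the 19 others, belonged to the 8 arrays high on the second component, so that set and array group overlapped. The number depended on nearly every strain. It was 0 without BXD42, 3 without BXD34, 9 without BXD39, 12 without BXD33 and 14 without BXD40. It was 226 without BXD6, 251 without BXD28, 260 without BXD36, 327 without BXD15, 393 without BXD8, 395 without BXD20, 421 without BXD23, 587 without BXD22 and 596 without BXD27. Without BXD2, BXD31, BXD12, BXD18, BXD1, BXD11, BXD19, BXD13, BXD14, BXD9, BXD21, BXD29, BXD16, BXD24 or BXD32 it lay between 24 and 50. It was 102 without BXD5 and 144 without BXD38.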

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

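The tests of spot effects, of gene expression as the source of the means, of printing place, of array components and of probe names were chosen after the results were seen; the splits of strains and the test against Gapdh spots were chosen before. Slc25a4 drew attention because 1 of the 7 strains numbered from 33 lay far from the others. BXD33 had −0.91 and the next lowest strain −0.09, a gap of 0.765 of the range. 20 genes were examined in this way, and chance picks out about 1 in 20.

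Mean log ratios lay away from 0 for most genes. As the main source, a difference in expression of the gene was argued against by probes of the same gene, provided that their symbols are right. Their means correlated with r = 0.0336 (95% interval −0.0270 to 0.0940, 1048 genes). Printing place as the main source was argued against by its share of 20.5% of the variance of named probes' means. A fixed effect of the spot or its dye may be a large part of these means. Of the Gapdh spots, annotated to 1 transcript, 81.4% differed from 0, in both directions. These spots lay in 4 of 48 blocks and were taken at the eighth place only, so they bear directly on that place alone. Probes of a gene can also detect different transcripts, and part of the probes may carry a wrong symbol. Neither was tested, and either would lower the correlation of probe means. Differences between the strains and C57BL/6J in single genes therefore stay open.

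Ribosomal protein genes covaried over the strains with a mean correlation of 0.432, which lies far above random lists and argues against probe names that belong to none of their spots; wrong names for part of the probes stay open, as probes of a gene had a median correlation of 0.0265. The first 3 array components as the whole cause were argued against by a mean correlation of 0.219 with them removed (95th percentile of random lists 0.0160). An effect shared by abundant transcripts could be neither shown nor excluded, since the mean correlation with Gapdh spots was 0.0188 against a 95th percentile of 0.0236 (one-sided permutation p = 0.0983), and that of oxidative phosphorylation genes was −0.00895 (permutation p = 0.822). Oxidative phosphorylation genes shared the pattern, with a mean correlation of 0.148 to ribosomal genes after removal of the components (95th percentile 0.0260). Differences between strains, between RNA preparations and between array groups all stay open, as each strain had 1 array.

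The 102 features that differed between strain sets were exceeded or equalled in 3 of 100 splits into 7 and 24, the real split included. This share lies under 0.05 but cannot exclude a chance overlap of strain number with array group. The number of features was unstable, from 0 without BXD42 to 596 without BXD27, and a random split gave 107. The highest other split gave 489. A split with several times the real number points to a structure of the arrays. That split held 3 of the 7 arrays apart on the first component, and what else it shares was not tested. The 7 strains from 33 held 5 of the 8 arrays high on the second component, so set and array group overlap. With the first 3 components as covariates 0 features passed in the real split and at most 1 in any other, so that setting does not tell the splits apart. The median difference of the 71 named genes went from 0.48 to 0.24 in size with these covariates. Its median SE was 0.10 in both, and all 71 kept their sign. These genes had been picked by this same difference on the same arrays. The starting size can therefore be inflated, and the kept signs say little.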

How the results depend on the processing

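All alternatives on the first 3 components, on arrays or strains left out, on eighth-place probes and on neighbouring genes other than the value over all genes were chosen after the data were seen, as was leaving out BXD6. For the mean, centring, robust eBayes, the Wilcoxon signed-rank test, single probes, named genes alone and leaving out the 7 arrays gave numbers within 1.5 times the 16176 reported. Treat against 1.2-fold gave 5938, since it asks for a larger change, and genes with no eighth-place probe 9781, since fewer were tested. Of 124 named genes, 28 no longer passed against 1.2-fold, and none of those that passed turned sign under 5 alternatives; Hba-a1, which did not pass, went from 0.01 to −0.00 with centring and −0.06 in the Wilcoxon test. Without the 7 arrays Clock went from −0.71 to −0.46, Pvalb from −0.19 to −0.11 and Wdfy1 from −0.13 to −0.21. The spread test gave 0 throughout.

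For strain sets, 67 features passed with the first component as a covariate, 190 by the Wilcoxon rank-sum test, 0 with the first 3 components and 3375 without the 7 arrays. Leaving out 1 strain gave 0 to 596. Of the 20 named genes, 10, 6, 20 and 0 no longer passed in these 4 alternatives. For division into 2 parts, 273 features passed with at least 8 strains on each side, 7 with the first component removed, 0 with the first 3 removed and 155 without the 7 arrays. All 15 named genes were lost on removal of components, 2 with 8 strains on each side and 4 without the 7 arrays. The cause was not tested.

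The difference of neighbouring genes did not pass within 30 places (0.000186), within 100 places (6.80e-05) or with the first 3 components removed (3.81e-05). It passed in the tenth of genes with the widest interquartile range (0.00413) and was −0.000114 there with the first component removed. The median correlation of probes was 0.00589 with the first component removed, and did not pass, whereas it passed by Spearman (0.0252) and with the first 3 components removed (0.0221). Covariation was called for 3 lists as deposited, 4 with the first component removed, 6 with the first 3 removed, 5 when BXD6 was also left out and 3 without the 7 arrays, where astrocyte genes replaced the cerebellar list. The cause was not tested. Camera called 0 lists under each alternative.

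Filters on missing values removed nothing, scaling equals centring for these columns, and centring is a common shift that leaves spread, parts, neighbours and set differences as they were, so these gave no further values. The designed population of neighbouring genes was empty. Signal over background was unknown, and the number of arrays limits all results.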

Other observations

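The scan of lists on single strains, the removal of 3 components and the choice of pituitary genes on BXD6 came after results were seen; the 2 tests of the BXD6 pattern were written before their results. With the first 3 components removed, myelin genes covaried with a mean correlation of 0.137 (one-sided permutation p = 0.0001, adjusted p = 0.000833), positive for 11 of 13 members. Mog, Mbp and Sox10 had the highest correlations with the rest of the list, 0.288, 0.271 and 0.230. Pituitary genes then had 0.187 (permutation p = 0.0002, adjusted p = 0.00125), led by the gonadotropin gene Lhb at 0.358, Pomc at 0.356 and Prl at 0.331, and 0.148 when BXD6 was left out (adjusted p = 0.00625). Cerebellar genes had 0.0737 and immediate early genes 0.0695 (each adjusted p = 0.0417), but immediate early genes did not pass when BXD6 was also left out (0.0619, adjusted p = 0.0654). With the first component alone removed, an alternative fixed in advance, immediate early genes had 0.118 (adjusted p = 0.0317) and myelin genes 0.104 (adjusted p = 0.0375), and both passed. Without the 7 arrays apart on that component, astrocyte genes passed at 0.182 (adjusted p = 0.0292), whereas myelin genes at 0.0496 (adjusted p = 0.247) and pituitary genes at 0.0379 (adjusted p = 0.400) did not.

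Over 775 pairs of a list and a strain, 63 mean deviations from the median of the other strains passed the threshold (100000 random lists, for which 1e-05 is the smallest p), 26 of them for ribosomal and 18 for oxidative phosphorylation genes. These p-values are too small because random lists lack the covariation of members. Ribosomal genes deviated by 0.63 on BXD32 and 0.54 on BXD5, and by −0.53 on BXD8 and −0.49 on BXD38. Oxidative phosphorylation genes deviated by 0.57 on BXD32 and −0.40 on BXD8. For both lists, the sign of the deviations past the threshold followed the array groups. These deviations were all negative on arrays apart on the first component or high on the second, and all positive on the remaining arrays. Cerebellar genes deviated by −0.41 on BXD8, where 0 of 12 lay above the median of the other strains. Y-linked genes and Xist passed on 4 strains, pituitary genes and GABA-A receptor subunits on 3 each, cerebellar and hypothalamic genes on 2 each, and microglial, heat shock, private-variant, glutamate receptor and immediate early genes on 1 each.

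Log ratios of pituitary hormone genes were high on the BXD6 array, with a mean deviation of the list of 0.97 (permutation p = 1e-05, adjusted p = 0.000267). The growth hormone gene Gh had 3.37 against at most 2.46 on the other arrays, Prl 2.58 against 1.53, Cga 2.42 against 0.90 and Pomc 2.19 against 0.33, whereas Lhb ranked 2 and Tshb, Fshb and Ghrhr 29 of 31. Pituitary tissue in the pool, which needs strain over C57BL/6J as the direction, stays open; in the other direction these genes would be low on BXD6. On a second list of 13 measured pituitary genes BXD6 ranked 30 of 31 strains with a mean deviation of −0.12, which the prediction written beforehand took as evidence against tissue, but many of these genes are regulators or expressed in brain and could hide a small share; 5 of the 13 lay above the median, with Pitx1 at 0.93 and the receptor genes Avpr1b at −0.58, Gnrhr at −0.36 and Trhr at −0.19. On BXD6, 0.444% of named genes lay over 1.5 from the median of the other strains. Deviations of that size were therefore not general on this array. The common distribution of the arrays limits such deviations, so this share cannot exclude smaller ones over the whole array. BXD6 was among the 7 arrays apart on the first component, with a mean correlation of 0.48 with the other arrays. A strain difference and an error of these spots stay open too, as 1 array of 1 pool was measured.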
